A study of Rattus norvegicus with 8 samples.

How the data were processed

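The scanner export of each of the 8 arrays gave, per the file headers, background-subtracted and spatially detrended spot intensities from Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09 on array design 028279. The unit of the signal was the scanner intensity, per the file headers, and log2 values were computed here. Of 62976 spots, 58717 were not controls and 4259 were controls. The main values were log2 of the processed signal minus the 75th percentile of the array, so they are log2 signals relative to that percentile. Replicate spots of a probe were averaged, and spots that the scanner software marked as outliers were left out unless all spots of the probe were marked. This rule was set after the signals had been opened. The 30367 probes comprised 13137 with 1 spot, 15840 with 2 and 1390 with 10, and 17998 had a gene symbol (15154 symbols) while 12369 had none. A probe was tested if it was well above background on every array of at least 1 group, which left 23585 probes and 12148 genes.

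The deposited log2 matrix held 22018 probes and served as an alternative. Its values had correlations of 0.999 to 0.9999 with log2 of the scanner signals, with medians from 9.82 to 10.33, so they were not normalized between arrays. Per the authors' labels, RNA with an integrity number under 8.0 was discarded. The array design was built on genome build rn4 and the reference table on GRCr8, so probes were matched to symbols by RefSeq accession and no coordinates are reported.

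Differences were tested in 1 limma fit of 8 arrays with 3 group means (limma 3.58.1, R 4.3.3), with 5 residual and 1.93 prior degrees of freedom, and p-values were adjusted over all tested probes by the Benjamini-Hochberg method at 0.05. The number of arrays limits the precision, and so does the unstated origin of the replicates. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The comparisons were P61S/R100E with P61S, P61S/R100E with wild type and P61S with wild type. The comparison of P61S/R100E with the mean of P61S and wild type was added after the data were seen.

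Gene lists, 19 in all, were fixed before the signals were opened: nociceptor channels and receptors, neuropeptides and vesicle cargo, early genes and ERK feedback, neurotrophins and GDNF family ligands and receptors, axon injury, apoptosis and survival, pan-neuronal, large-diameter neuron, satellite glia, Schwann cell, fibroblast, macrophage, endothelial and mural, cell cycle, inflammatory mediators, cholesterol synthesis, endoplasmic reticulum stress, glycolysis and hypoxia, and interferon-induced genes. The brightest probe stood for each gene. The planned test was camera with a preset correlation of 0.01, and its alternatives, also set beforehand, were camera with an estimated correlation and fry in one direction. Tests of change in either direction were added after the data were seen, first with fry and then with roast (9999 rotations, mean statistic and mean square). Roast replaced fry because, in 20 simulations of unchanged arrays with 380 list tests, fry called 12 lists in 8 simulations, roast 3 lists in 2 simulations and camera 0. When 1 list was changed 1.5-fold in both directions, fry and roast called it in 20 of 20 simulations and camera in 0. Its members rose and fell in turn, so camera, which tests a shift of the whole list, could hardly call it. Simulated probes varied independently and roast used fewer rotations there, so these rates may not hold for the real arrays. List members were also adjusted over the list alone, a reading taken after no member passed over all probes.

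Named genes were those past an adjusted p of 0.05, else the 5 with the smallest p in each direction. Both were taken only from genes whose compared groups did not overlap, so the separation of those groups was fixed by the rule. Added to these were up to 4 members per direction of each list past the test adjusted over the list alone, and 12 genes fixed beforehand. Some items that these rules take, among them 1 of the 12 fixed genes and a hypothesis tested, are not reported here. For probes in a group below background, a lower bound of the fold is given, and its values without each array were computed after the data were seen. In simulated data with 50 probes changed at each of 1.5, 2, 4 and 8-fold together, the comparison with P61S recovered 12, 29, 48 and 48. It called 5 unchanged probes. The larger changes ease the adjusted threshold for the smaller ones, so recovery can be lower where few probes change.

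Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, centring on the median of detected probes, the deposited values, no filter, a filter on all arrays, the replicate number as a block, the slide row as a block, a fit of only the 2 groups compared, a variance trend with robust hyperparameters, each array left out, an adjusted p under 0.10, and a change of at least 1.5-fold. Normexp was set beforehand to use the mean spot signal; the median spot signal was used instead, a change made after the files were opened, and the mean is not used here. The slide column as a covariate, also with columns exchanged between the arrays of a group, was added after the data were seen. Probes without a symbol entered the tests but not the lists.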

Results

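Cultures of dissociated dorsal root ganglia, the clusters of sensory neurons beside the spinal cord, came from newborn Wistar rats of both sexes. They received a human protein at 100 ng/ml for 5 days in 1 of 3 forms. These were the P61S mutant (n = 3 arrays), the P61S/R100E double mutant (n = 3 arrays) and the wild type (n = 2 arrays). No culture without the protein was analysed here. The arrays measured polyadenylated RNA of all cells in a culture, neurons and non-neuronal cells together. The labels do not say whether replicates came from separate cultures or animals, so every p-value measures only the spread between these samples.

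The 8 one-colour arrays carried 58717 spots each besides the controls, and their 75th percentile signals ran from 3267 (wild type replicate 2) to 5269 (P61S/R100E replicate 2). Between 78.7% and 88.8% of the spots on an array were well above background, and 0 spots were saturated. The number of arrays limits the precision. Across probes, which are not independent replicates, wild type replicate 2 had correlations of 0.983 to 0.989 with the other 7 arrays. All pairs without it lay between 0.99 and 0.996. On the first principal component, which held 35.9% of the variance, wild type replicate 2 stood at 68.3 and the other arrays between -27.9 and 19.1. The 3 P61S/R100E arrays spanned -27.9 to -3.2 on that component and -18.6 to 41.8 on the second, so they did not form a group of their own on either.

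**Figure D1:**
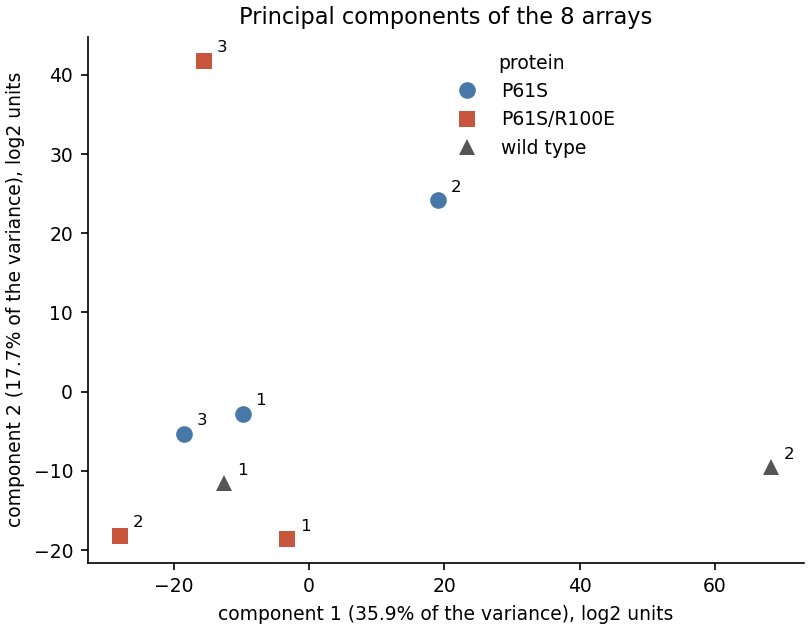
Principal components 1 and 2 of the log2 signals of the 8 arrays, in log2 units; each point is an array, its colour and shape give the form of the protein and its number the replicate. Wild type replicate 2 stands at 68.3 on component 1, beyond the next array at 19.1.

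The comparison of P61S/R100E with P61S asks what the R100E change does in a protein that already carries P61S. Vip (probe A_64_P096924), which encodes vasoactive intestinal peptide, was 3.21-fold higher with P61S/R100E (log2 change 1.68, SE 0.157). Its log2 signal relative to the array's 75th percentile was 1.44 ± 0.11 with P61S/R100E and -0.24 ± 0.30 with P61S (SD, n = 3 each). Il24, a cytokine of the interleukin-10 family, was 2.72-fold higher (log2 change 1.45, SE 0.188), and Pde6b, a subunit of the rod phosphodiesterase, 2.26-fold higher (log2 change 1.18, SE 0.132). Anxa3, a calcium-dependent phospholipid-binding protein, was 1.92-fold higher and the secreted cysteine-rich protein gene Crisp3 1.77-fold higher. Lrat (probe A_44_P550748), the enzyme that esterifies retinol for storage, was 2.23-fold lower (log2 change -1.16, SE 0.0847), at -4.49 ± 0.09 against -3.33 ± 0.08 (SD, n = 3 each). Mrgprb5, a Mas-related G protein-coupled receptor, differed by -0.81 (SE 0.105), Calb2, which encodes the calcium-binding protein calretinin, by -0.69 (SE 0.0795), and Cldn3, a tight junction claudin, by -0.64 (SE 0.0843). In each of these 9 genes the 3 P61S/R100E arrays lay outside the range of the 3 P61S arrays, which the rule for naming them required.

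Among genes whose 2 groups did not overlap, these had the smallest p-values in each direction, and they did not pass the test over all probes. limma called 0 of 23585 probes at an adjusted p under 0.05, and the smallest adjusted p was 0.068, for Lrat. At an unadjusted p under 0.05 there were 946 probes (457 higher, 489 lower), where chance gives 1179. With a trend of the variance on signal and robust hyperparameters, limma called 6 probes, for Vip, Anxa3, Crisp3, Lrat, Calb2 and a probe without a gene name, and without P61S replicate 2 it called 3, for Vip, Il24 and a probe without a gene name. Simulated data of this layout held probes changed from 1.5-fold to 8-fold together. There the same test recovered 29 of 50 probes changed 2-fold and 48 of 50 changed 4-fold. With 0 calls the adjusted threshold is stricter, so these shares can overstate the recovery here.

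Neuropeptide genes changed in both directions between P61S/R100E and P61S. Of 25 measured members of the list of neuropeptides and vesicle cargo, 7 passed when adjusted over the list alone (2 higher, 5 lower) and 0 passed over all probes. Vip rose, as did Gal, the galanin gene (log2 change 0.46, SE 0.136, 1.37-fold). Nts, which encodes neurotensin, fell by 1.05 (SE 0.149), and Nppb, a natriuretic peptide gene of itch neurons, fell by 0.76 (SE 0.143). Smaller decreases were measured for Adcyap1, the gene of the peptide PACAP (-0.34), for the neurotrophin Bdnf (-0.29) and for Calcb, a calcitonin gene-related peptide gene (-0.27, SE 0.0746). Tac1, the substance P gene (-0.07, 95% bounds -0.32 and 0.18), and Calca (-0.13, 95% bounds -0.46 and 0.20) did not pass. A second Calca probe gave -0.42 and did not pass over all probes. In roast, a rotation test of change in either direction, the list had an adjusted p of 0.0019 over 19 lists. It did not pass with the slide column of the arrays as a covariate (adjusted p = 0.31).

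Receptors of nociceptors, the neurons that sense painful stimuli, were the next list to pass. Of 29 measured members 4 passed when adjusted over the list alone, and 0 passed over all probes. P2rx2, an ATP-gated channel, rose by 0.54 (SE 0.0958, 1.45-fold). F2rl1, the protease-activated receptor PAR2 (-0.69, SE 0.0938), Mrgprb5 and Ptger3, a prostaglandin E2 receptor (-0.66, SE 0.123), were lower than with P61S. Ptger3 differed by 0.17 (SE 0.138) against wild type and did not pass there, so P61S was the group with the higher signal. Trpv1, the capsaicin receptor, differed by -0.27 (SE 0.0954), Scn10a by -0.21 (SE 0.0847) and Scn9a by -0.07 (SE 0.127), which did not pass. The bradykinin receptor gene Bdkrb2 differed by 0.15 (SE 0.262) and Ngfr, of the tumour necrosis factor receptor family, by 0.08 (SE 0.0895), with no pass either. The list had a roast adjusted p of 0.0028. It did not pass with the slide column as a covariate (adjusted p = 0.75), without P61S replicate 1 (0.18) or without P61S replicate 3 (0.065).

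Genes known from injured axons moved apart as well. Of 32 measured members 5 passed when adjusted over the list alone, and 0 passed over all probes. Vip and Cckbr, a cholecystokinin receptor (log2 change 1.05, SE 0.152, 2.06-fold), rose. Reg3b (-0.52, SE 0.086), Reg3a (-0.48, SE 0.0806) and Adcyap1 fell, the first 2 being secreted lectins that sensory neurons induce after nerve damage. The injury transcription factor Atf3 differed by 0.21 (SE 0.0828) and did not pass. A second Cckbr probe gave 0.35 and did not pass. The list had a roast adjusted p of 0.0032, but 0.49 with the slide column as a covariate, and its 28 members outside the neuropeptide list had a roast p of 0.0011.

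**Figure D2:**
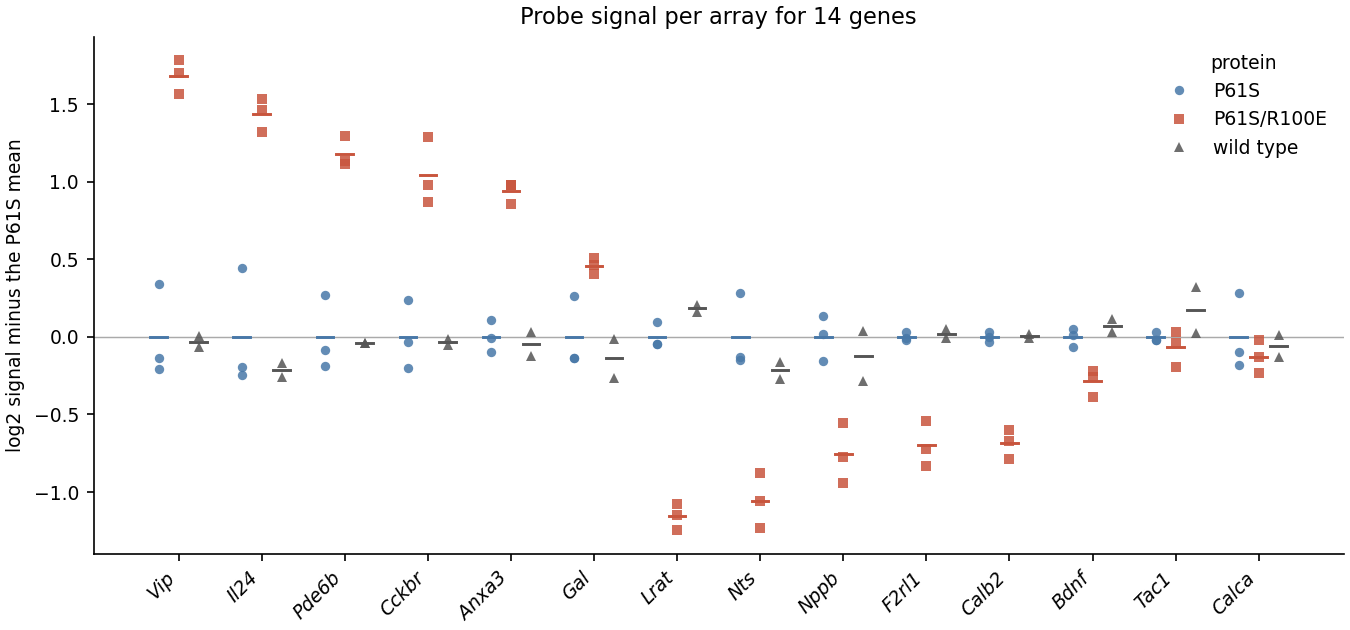
Log2 probe signal of 14 genes on each array, given as the difference from the P61S mean of that gene; each point is an array, short lines are group means, and colour and shape give the form of the protein. Vip differs by 1.68 and Lrat by -1.16 with P61S/R100E, while Tac1 (-0.07) and Calca (-0.13) did not pass when adjusted over the list alone.

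The test of a shift in one direction, camera, called 3 of 19 lists at its preset correlation. Cholesterol synthesis genes rose on average (mean log2 change 0.10, median 0.09, 21 members, adjusted p = 9.5e-04). The growth-factor-induced early genes and ERK feedback genes fell (mean -0.15, median -0.12, 31 members, adjusted p = 0.015), and so did the glycolysis and hypoxia genes (mean -0.16, median -0.11, 23 members, adjusted p = 0.033). No call held with an estimated correlation, where the adjusted p was 0.5, 0.65 and 0.72 in the same order. Under 19 alternative settings, left-out arrays included, the calls ended in 0, 3 and 8 in that order. The mean of the glycolysis and hypoxia genes ran from -0.327 to -0.021. Camera called 6 lists without P61S replicate 2, 7 without P61S replicate 3 and 9 without P61S/R100E replicate 2. Among single members, Hrk, a pro-apoptotic BH3-only gene, rose by 0.44 (SE 0.0815) when adjusted over the list alone. A second Hrk probe gave -0.02. Calb2 was the only member of the large-diameter neuron list past that test.

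No list of cell type markers passed camera or roast between the same groups, while fry in either direction, a related rotation test, called the large-diameter neuron markers (adjusted p = 2.0e-06). The median log2 change was 0.04 for 23 pan-neuronal markers, 0.00 for 18 satellite glia markers, -0.01 for 24 Schwann cell genes and 0.03 for 23 fibroblast genes. It was 0.08 for 21 macrophage markers, -0.16 for 13 endothelial and mural markers (mean -0.18, camera adjusted p = 0.07) and -0.05 for 17 markers of large-diameter neurons. In roast the adjusted p was 0.6 for pan-neuronal markers, 0.83 for satellite glia, 0.59 for Schwann cells, 0.5 for both fibroblasts and macrophages, 0.67 for endothelium and 0.22 for large-diameter neurons. It was 0.094 for ERK feedback, 0.096 for inflammatory mediators, 0.23 for neurotrophins and their receptors and 0.25 for cholesterol synthesis. Apoptosis, glycolysis and hypoxia, and interferon-induced genes were at 0.59 each, and cell cycle and endoplasmic reticulum stress genes at 0.79 each. Neurotrophin, cell cycle and inflammatory genes had a mean of -0.01 but medians of 0.01, 0.02 and 0.05, with camera's direction up.

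Roast thus called 3 of 19 lists, its mean square form 4, and fry 6 in either direction and 0 in one direction. The mean slide column of the arrays was 1.33 for P61S, 2.67 for P61S/R100E and 4 for wild type, with 1 array each of P61S and P61S/R100E in the same column. With the column as a covariate roast called 0 lists, while the median SE over genes grew from 0.118 to 0.207. The 17 members past the test adjusted over the list alone in any list kept their direction, with a median absolute change of 0.54 without the column and 0.57 with it. Their choice by passing without the column favours that result. Gal went from 0.46 (SE 0.136) to 0.14 (SE 0.198).

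**Figure D3:**
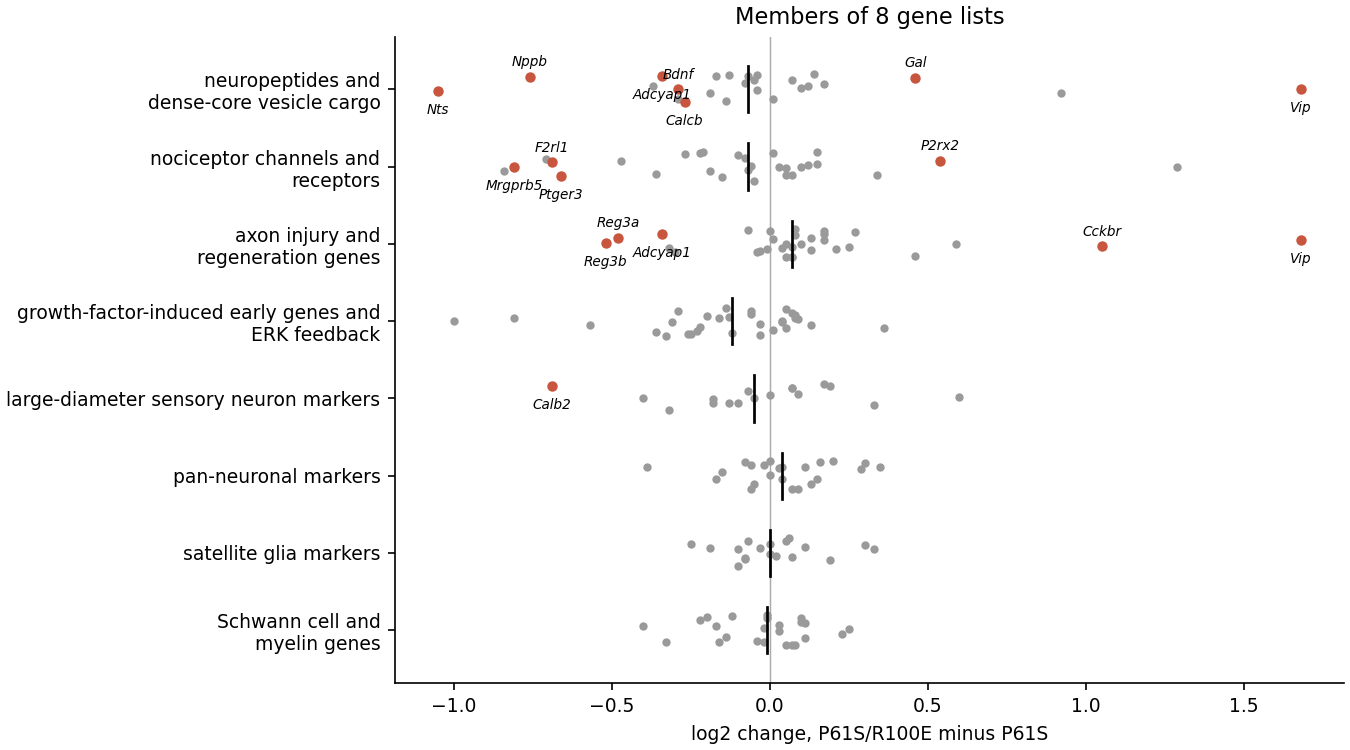
Log2 change between P61S/R100E and P61S of each measured member of 8 gene lists; each point is a gene, black bars are medians, and red points with names passed when adjusted over the list alone. The neuropeptide list has 2 such members on the higher side and 5 on the lower, and its median is -0.07.

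Against the wild type protein, P61S/R100E was compared for the joint effect of both substitutions. Both wild type arrays lay in slide column 4 and no mutant array did. An effect of that column therefore cannot be told apart from the protein in any comparison with wild type. Vip was 3.29-fold higher (log2 change 1.72, SE 0.175), at 1.44 ± 0.11 (SD, n = 3) against -0.28 ± 0.05 (SD, n = 2). Il24 was 3.14-fold, Pde6b 2.32-fold, Anxa3 1.98-fold and Crisp3 1.78-fold higher. Lrat was 2.53-fold lower (log2 change -1.34, SE 0.0947), Camk4, a calcium/calmodulin-dependent kinase of neurons, 1.75-fold lower (-0.81, SE 0.111), and F2rl1 (-0.72), Calb2 (-0.69) and Cldn3 (-0.66) were lower by less. The 3 P61S/R100E arrays are the ones already compared with P61S, so the 2 sets of values are not independent. None of these genes passed over all probes. limma called 0 of 23585 probes, with the smallest adjusted p at 0.054 for Lrat and 1188 probes (377 higher, 811 lower) at an unadjusted p under 0.05, where chance gives 1179.

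The same 3 lists passed roast against wild type. Among neuropeptide genes 5 of 25 members passed when adjusted over the list alone: Vip and Gal (0.60, SE 0.152) rose, and Nts (-0.84), Nppb (-0.63) and Bdnf (-0.36) fell. Among nociceptor receptors P2rx2 rose (0.61, SE 0.107), and F2rl1, Mrgprb5 (-0.75, SE 0.117) and the irritant receptor Trpa1 (-1.13, SE 0.275) fell, 4 of 29 members. Among injury genes 7 of 32 members passed: Vip, Cckbr (1.08), Gal and Hspb1, a small heat shock protein (0.39), rose, and Reg3b (-0.47), Il6 (-0.41) and Reg3a (-0.40) fell. The roast adjusted p was 0.0019 for neuropeptides, 0.041 for nociceptors and 0.0095 for injury genes, whose 28 members outside the neuropeptide list had a roast p of 0.0018. Over all probes 0 members passed. Trpv1 (-0.30, SE 0.107), Tac1 (-0.24, SE 0.12), Vgf, a secreted peptide precursor (-0.28, SE 0.135), and Atf3 (0.23, SE 0.0926) did not pass when adjusted over the list alone.

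Camera called 4 lists against wild type at its preset correlation. Macrophage and other immune markers were higher (mean 0.09, median 0.15, adjusted p = 0.014), as were injury genes (mean 0.11, median 0.03, adjusted p = 0.016) and cholesterol synthesis genes (mean 0.05, median 0.06, adjusted p = 0.016). ERK feedback genes were lower (mean -0.23, median -0.13, adjusted p = 0.016). No call held with an estimated correlation, where the adjusted p was 0.35 for macrophages and 0.57 for each of the other lists. Pan-neuronal markers had a mean of -0.09 and a median of -0.07 while camera's direction was up, the median of all probes being -0.06. The same held for endoplasmic reticulum stress genes (mean -0.05, median -0.02), and cell cycle (mean -0.02, median 0.00) and satellite glia genes (mean -0.01, median 0.01) differed in sign as well. Fry called 8 lists in either direction and 0 in one direction, and the mean square form of roast called 4. Camera called 0 lists without wild type replicate 1.

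The calls against wild type changed with single arrays left out. Without a wild type array that group holds 1 array, and the spread comes from the other groups alone. Without wild type replicate 2, the array that stood apart, roast called 0 lists (adjusted p = 0.083 for neuropeptides, 0.083 for injury genes and 0.43 for nociceptors) and limma 1 probe. Without wild type replicate 1, which leaves only the array that stood apart, roast called 9 lists and limma 1244 probes. Without P61S replicate 2 limma called Vip and Il24. The nociceptor call ended without any array other than wild type replicate 1 (adjusted p from 0.08 to 0.43) and in 9 alternative settings (0.051 to 0.6). The injury call ended without P61S/R100E replicate 3 (0.082), and in alternative settings at 0.051 to 0.13. The neuropeptide call ended only without wild type replicate 2.

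The comparison of P61S with the wild type asks what the P61S substitution alone does. Here too slide column 4 held both wild type arrays and no P61S array, so column and protein are confounded. Ptger3 was 1.78-fold higher with P61S (log2 change 0.83, SE 0.138), Stfa2l1, a stefin-like protease inhibitor gene, 1.55-fold (0.63, SE 0.114), Oas2, an interferon-induced oligoadenylate synthetase, 1.49-fold (0.58, SE 0.103) and Alox5, the 5-lipoxygenase gene, 1.42-fold higher (0.50, SE 0.117). Rflna was higher by 0.44 on 1 probe and differed by -0.11 on another. The acid-sensing channel gene Asic2 was lower (-0.74, SE 0.163), as were the olfactory receptor genes Or10x1b (-0.72, SE 0.158) and Or51e1 (-0.65, SE 0.124) and the lectin-like gene Clec2g (-0.42, SE 0.0936). Asic2 and Or10x1b were well above background on only 2 of 3 P61S arrays, so part of their decrease was read near background. Ptger3, read from 1 spot, was well above background on every array. Its wild type log2 signal (-7.05) was nonetheless about as low as that of Or10x1b with P61S (-7.10). Tnfsf4, the OX40 ligand gene, was above background on both wild type arrays and on no P61S array, at least 5.16-fold higher with wild type (log2 signals -5.81 ± 1.37, SD, n = 2). That bound was 2.63-fold without wild type replicate 2 and 10.1-fold without wild type replicate 1.

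Among genes whose 2 groups did not overlap, these had the smallest p-values, and they did not pass the test. limma called 0 of 23585 probes (smallest adjusted p 0.29), with 489 probes (163 higher, 326 lower) at an unadjusted p under 0.05, where chance gives 1179. Camera called 0 of 19 lists at either correlation (3 at an unadjusted p under 0.05 with the preset one), fry 0 in one or either direction and roast 0 in both forms. The lowest roast adjusted p was 0.87, and 0.84 in the mean square form, and only Ptger3 passed when adjusted over the list alone. Camera's direction was up for large-diameter neuron (mean -0.09), satellite glia (mean -0.02, median -0.06) and cell cycle genes (mean -0.01, median -0.04). The interval of the difference between P61S and wild type was -0.25 to 0.22 for Ngfr, -0.28 to 0.23 for Trpv1, -0.30 to 0.43 for Calca and -0.29 to 0.15 for Bdnf (95%, log2). In simulated data the test recovered 8 of 50 probes changed 1.5-fold and 33 of 50 changed 2-fold. Those data also held larger changes, which ease the adjusted threshold, so these shares can overstate the recovery here. Without wild type replicate 1, with 1 array left in that group and the spread taken from the others, limma called 250 probes. It called 1 without wild type replicate 2, where the same limit holds, or without P61S replicate 2. Camera called 1 list without P61S replicate 2.

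Because P61S and wild type did not differ in these tests, P61S/R100E was also set against the mean of both groups, a comparison chosen after the data were examined. Lrat fell by 1.25 on the log2 scale (SE 0.0763, 2.37-fold lower), and it alone of 23585 probes passed in limma (adjusted p = 0.02). Its 3 P61S/R100E arrays lay below the other 5, as the rule for naming required. A second Lrat probe gave -1.48 and did not pass. Vip (1.70, SE 0.141) and Anxa3 (0.96, SE 0.0836) followed, each with an adjusted p of 0.071. Roast called the neuropeptide (adjusted p = 0.0019), injury (0.0019), nociceptor (0.0076) and inflammatory mediator (0.035) lists, and the injury genes outside the neuropeptide list had a roast p of 3.0e-04. A linear trend over the slide columns cancels in this comparison, since the mean column of P61S/R100E equals that of the other groups' means. The inflammatory list had a mean of -0.03 and a median of 0.03, and 0 of its members passed when adjusted over the list alone. With the column as a covariate the neuropeptide (0.0095), injury (0.0095), nociceptor (0.025) and inflammatory (0.032) lists passed. That covariate could not move the log2 changes here, so these passes are no separate check. The inflammatory call ended with normexp (0.077), with the median of detected probes (0.051) and with the replicate numbers as a block (0.1). It also ended without P61S replicate 1 (0.15), 2 (0.08) or 3 (0.11), P61S/R100E replicate 1 (0.071) or 3 (0.18), or wild type replicate 2 (0.17). Mean square roast called 6 lists, fry 9 in either direction and 0 in one, and camera 4: cholesterol synthesis (adjusted p = 0.0028), ERK feedback (0.011), macrophage (0.011) and injury genes (0.021). With an estimated correlation camera called 0, at adjusted p = 0.32, 0.54, 0.32 and 0.54. The adjusted p of Lrat ran from 0.011 to 0.42 over the alternative settings and passed without P61S replicate 2 (0.032) or wild type replicate 1 (0.04) but did not pass without any of the other arrays (0.073 to 0.29).

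In the same comparison single arrays moved the counts. Without wild type replicate 1, with 1 array left in that group, limma called 24 probes, roast 8 lists and camera 0, and without P61S replicate 2 limma called 4 probes, for Vip, Il24, Pde6b and Lrat. Roast called 2 lists without P61S replicate 1 or P61S/R100E replicate 1, and 1 list, the neuropeptides, without P61S/R100E replicate 3. The injury list then had an adjusted p of 0.051. The nociceptor list did not pass without P61S replicate 1 (0.081) or without P61S/R100E replicate 1 (0.067), 2 (0.068) or 3 (0.054). Nor did it pass with the replicate numbers as a block. Camera called 7 lists without P61S replicate 1 or P61S/R100E replicate 2 and 2 without P61S/R100E replicate 3.

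Both mutants were compared with the same 2 wild type arrays, and limma called 0 probes in both comparisons. At an unadjusted p under 0.05, 32 probes were higher and 160 lower with both mutants. Independent comparisons would give 2.61 and 11.2, and 20 simulations of unchanged groups that share 2 arrays gave means of 194 (range 175 to 213) and 187 (range 172 to 209), so both counts lay below the simulated ranges. The wild type arrays were not split between the comparisons, which would have left a single array for each. Across probes the log2 changes of both mutants had a correlation of 0.678, above the simulated values (mean 0.599, range 0.586 to 0.62). The simulation gave all arrays the same spread within a probe, whereas wild type replicate 2, used in both comparisons, stood apart. The simulated ranges may therefore not hold for these arrays. The cause of these departures was not tested.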

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

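Of the 3703 gene and list values under the alternatives, 3510 stayed the same, 89 became weaker, 67 stronger and 37 reversed. The same means the same side of the threshold and, except for the roast values, which have no direction, the same direction. Few of these values were past the threshold in the main fit, so the count mostly shows that calls stayed absent. The slide column, the comparison of P61S/R100E with the mean of both other groups and the tests in either direction were chosen after the data were seen. The cause was not tested where none is given. Without a wild type array that group holds 1 array, and its spread comes from the other groups alone.

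With P61S/R100E against P61S, limma called 0 probes. It called 1 at an adjusted p under 0.10 (a wider threshold by construction), 1 (Lrat) with the deposited values, 1 (Lrat) with probes well above background on every array, 6 with a variance trend and robust hyperparameters, and 0 to 3 with an array left out (3 without P61S replicate 2). The 3 list shifts of camera became 0 with an estimated correlation, 0 with fry in one direction, 1 with the slide row as a block, 5 with the slide column as a covariate and 2 to 9 with an array left out (6 without P61S replicate 2, 7 without P61S replicate 3, 9 without P61S/R100E replicate 2). The 3 lists of roast became 6 with fry in either direction and 0 with the slide column, where the residual degrees of freedom fell from 5 to 4 and the median SE grew from 0.118 to 0.207. The 17 members past the test adjusted over the list alone kept their direction with the column, and their median absolute change was 0.54 without it and 0.57 with it. Their choice by passing without the column favours that result. Gal went from 0.46 (SE 0.136) to 0.14 (SE 0.198). Over the alternatives Ptger3 ran from -0.97 (slide column) to -0.22 (normexp), with a main value of -0.66, and Mrgprb5 from -0.87 (slide column) to -0.37 (deposited values), with a main value of -0.81.

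With P61S/R100E against wild type, limma called 0 probes. It called 1 at an adjusted p under 0.10, 1 (an unnamed probe) with normexp and with quantile normalization, 1 (Lrat) with the deposited values and with probes well above background on every array, 1 (Vip) with a variance trend, and 0 to 1244 with an array left out (2 without P61S replicate 2, 1244 without wild type replicate 1, 1 without wild type replicate 2). The 4 list shifts of camera became 0 with an estimated correlation, 0 with fry in one direction, 2 with normexp and 0 without wild type replicate 1. The 3 lists of roast became 8 with fry in either direction, 1 with normexp, 1 with the replicate block, 1 with only the arrays of both groups compared, and 0 to 9 with an array left out (1 without P61S/R100E replicate 3, 9 without wild type replicate 1, 0 without wild type replicate 2).

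With P61S against wild type, limma called 0 probes, 1 with normexp, 1 with quantile normalization and 0 to 250 with an array left out (1 without P61S replicate 2, 250 without wild type replicate 1, 1 without wild type replicate 2). Camera called 0 lists, 1 with no filter, 1 with the replicate block, 3 with the slide column and 0 to 1 with an array left out (1 without P61S replicate 2). Roast called 0 lists under every alternative. The overlap of both mutants against wild type was 0 probes, 1 with normexp, 1 with quantile normalization, 248 without wild type replicate 1 and 1 without wild type replicate 2.

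With P61S/R100E against the mean of P61S and wild type, the 1 probe (Lrat) became 8 at an adjusted p under 0.10, 9 with normexp, 2 with the median of detected probes, 3 with the deposited values, 0 with no filter (more probes tested), 3 with probes well above background on every array (fewer tested), 0 with the replicate block, 0 with the slide row, 9 with a variance trend and 0 with the slide column. With quantile normalization the count stayed at 1, but the probe was an unnamed one and Lrat had an adjusted p of 0.066. With an array left out the count was 0 to 24 (4 without P61S replicate 2, 24 without wild type replicate 1, 0 without any of the other arrays). The 4 list shifts of camera became 0 with an estimated correlation, 0 with fry in one direction, and 0 to 7 with an array left out (7 without P61S replicate 1, 7 without P61S/R100E replicate 2, 2 without P61S/R100E replicate 3, 0 without wild type replicate 1). The 4 lists of roast became 9 with fry in either direction, 2 with the replicate block and 1 to 8 with an array left out (2 without P61S replicate 1, 2 without P61S/R100E replicate 1, 1 without P61S/R100E replicate 3, 8 without wild type replicate 1). The residuals of P61S and P61S/R100E arrays with the same number had correlations of 0.05, -0.02 and 0.01 across probes. Those of wild type arrays had 0.10 and 0.17 with P61S and -0.16 and -0.20 with P61S/R100E.

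P61S/R100E against wild type gave for Calca -0.07, but 0.15 with normexp, 0.01 with the median of detected probes, 0.32 with the slide column and -0.14 to 0.00 with an array left out. Scn10a was 0.00, with 0.11 with normexp, 0.07 with the median, 0.00 with the deposited values, 0.00 with the replicate block and -0.09 to 0.08 with an array left out. Scn9a was -0.05, with 0.03 with the median and -0.13 to 0.09 with an array left out. Bdkrb2 was -0.29, with 0.14 with the slide column and -0.66 to 0.08 with an array left out, and Ngfr 0.06 with -0.04 to 0.17. P61S/R100E against P61S gave for Bdkrb2 0.15, but -0.28 with the slide column, for Scn9a -0.07, but 0.07 with the slide column and -0.15 to 0.07 with an array left out, and for Calca -0.13, with -0.51 with the slide column and -0.22 to 0.01 with an array left out.

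P61S against wild type gave for Ngfr -0.02, with 0.01 with normexp, 0.00 with quantile normalization, 0.04 with the median, 0.14 with the slide column and -0.12 to 0.09 with an array left out. Vgf was -0.14, with 0.03 with normexp and 0.05 with the slide column. Trpv1 was -0.02, with 0.03 with the median and -0.12 to 0.08 with an array left out. Atf3 was 0.02, with 0.00 with the replicate block and -0.06 to 0.09 with an array left out. Tac1 was -0.18, with 0.15 with the slide column, Bdkrb2 -0.45, with 0.42, and Scn9a 0.02, with -0.24 and -0.01 to 0.06 with an array left out. Calca was 0.06, with 0.36 with normexp, 0.83 with the slide column and -0.08 to 0.15 with an array left out. Over the alternatives Ptger3 (main value 0.83) ran from 0.39 to 1.44, Asic2 (-0.74) from -0.85 to -0.26, Or10x1b (-0.72) from -0.88 to -0.20 and Or51e1 (-0.65) from -0.79 to -0.24. With the slide column the median change of all probes went from -0.04 to 0.11 for P61S against wild type and from -0.02 to -0.11 for P61S/R100E against P61S.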

Other observations

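The tests of the neuron share, of the slide column for 3 lists and of exchanged columns were chosen after the results were seen, as was the comparison with the mean of both other groups.

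Among early genes and feedback inhibitors of ERK, a kinase pathway of growth factor receptors, 4 of 31 measured members passed when adjusted over the list alone in the comparison of P61S/R100E with the mean of P61S and wild type, and 0 passed over all probes. Dusp5, an ERK phosphatase, fell by 0.58 (SE 0.114), Etv4, an ETS transcription factor, by 0.93 (SE 0.236; -1.17 to -0.57 over the alternatives) and Spry4, a Sprouty inhibitor, by 0.30 (SE 0.0739). A second Spry4 probe gave -0.32 and did not pass. The fourth, the immediate early gene Egr4, was above background on no P61S/R100E array, so bounds are given. It entered the test only because both wild type arrays were above background. Its measured change in this comparison ran from -1.46 to -0.23 over the alternatives. Egr4 lay at least 2.34-fold higher with wild type and at least 1.83-fold higher with P61S, which was above background on 2 of 3 arrays. The bound against wild type was 1.69-fold without wild type replicate 1 and 3.24-fold without wild type replicate 2. The list as a whole did not pass roast (adjusted p = 0.062), but did with quantile normalization (0.048) and without wild type replicate 1 (0.0057), which leaves 1 wild type array. Camera's call (adjusted p = 0.011) ended with an estimated correlation (0.54), without P61S/R100E replicate 3 (0.12) and without wild type replicate 1 (0.17).

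The arrays were also split in every other way. The 10 splits of the P61S/R100E and P61S arrays are too few for a share under 0.05: with fry 1 gave as many lists as the real one (6, others up to 3) and with roast 1 (3, others up to 0), and for probes, where the real count was 0 (others up to 5), all 10 met it by construction. Of the 56 splits of all arrays into 3 and 5 in a fit of 2 groups, 1 gave as many lists with fry (7, others up to 3) and 1 with roast (5, others up to 1), shares under 0.05, but the split of P61S/R100E from the rest was chosen after its differences were seen. For probes 2 splits gave as many: the real one called 21, and P61S replicates 1 and 3 with P61S/R100E replicate 3, a mix of both proteins, called 22. Chance is therefore not set aside for the probes, and the fit of 3 groups called 1 probe.

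The neuropeptide, nociceptor and injury lists could reflect the place of the arrays on the slide. With the column as a covariate 3 of 6 lists stayed with fry and 0 of 3 with roast against P61S. The covariate widened the median SE of 17 members from 0.0938 to 0.165. Their median absolute change was 0.57 with it and 0.54 without, all 17 in the same direction. These members were chosen for passing without the covariate, which favours that result. With the columns exchanged between the arrays of a group, which keeps the group means, 5 of 8 other assignments also left 0 of the 3 lists in roast, and 1 left all 3. Most covariates of this shape thus end the calls without holding the real columns, so the bounds written for these tests could not decide. Against wild type, with the real columns, the neuropeptide (adjusted p = 0.015) and injury (0.016) lists passed and the nociceptor list did not (0.6). Column 4 held only wild type arrays, so a numeric covariate cannot address an effect of that column. The explanation cannot be told apart. Against the mean of both other groups a linear trend over the columns cancels, so the covariate could not move the changes. The median SE was 0.106 without it and 0.108 with it. There 3 of 3 lists passed, which sets a linear trend aside for that comparison alone. A curved trend stays open, and the comparison with P61S is not decided. For a different share of neurons, the upper quartile of the absolute change of 23 pan-neuronal markers was 0.16, and their median change was 0.04. The 17 members had a median absolute change of 0.54, with 6 higher and 11 lower. They were chosen for passing in this comparison, which favours a large median, so the bound set against it could not decide. The values show only that the pan-neuronal markers did not shift by as much as those members.

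Wild type replicate 2 stood apart from the other 7 arrays, with a median SD of log2 differences of 0.533 against 0.384 to 0.474. The excess over the next array was 0.0583 before and 0.0829 after quantile normalization. This sets aside only a compressed scale of the kind that quantile normalization removes. The slope of the spike-in controls was 0.971 on this array and 0.957 on P61S replicate 2. On the other arrays it was 0.992 to 1.008, so a lower slope was measured here, and its part was not tested. A different cell makeup of that culture cannot be told apart: 2 of 7 cell type lists had their largest deviation on it, and chance gives 0.875 (binomial p = 0.21). That p takes the lists as independent, which lists read on the same arrays are not. Nor were the deviations corrected for the array's median over all genes (0.07). For large-diameter neuron markers the deviation was 0.19, close to 0.18 on P61S replicate 2. The bound written beforehand, at least 1 list, was too loose, as chance alone meets it.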
